A study of Arabidopsis thaliana with 20 samples.

How the data were processed

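RNA from Arabidopsis inflorescences was measured on 20 two-colour Agilent arrays, each with a Dex and a Mock sample of the same time and set. Per the labels' protocols, RNA was isolated with a plant RNA kit, checked on a Bioanalyzer and labelled with the Agilent Quick Amp kit, and the names of the scanner outputs in the labels point to Agilent Feature Extraction for two-colour arrays. The deposited values are log ratios, 1 per probe and array, read here as log10 ratios. This base was inferred from the default of Feature Extraction and from no header, so a fold change or log2 value holds only if it is right, while p-values do not depend on it. Normalization, background correction and filters are not given in the sources used here. The median over all rows was 0 on each array but 1, where it was 0.00534, in the deposited log10 unit, and over the tested probes it ran from -0.03 to 0.08 on the log2 scale. A table of combined ratios, also read as log10, was deposited by the authors with 1 column per time, and how the sets were weighted in it is not given in the sources used here.

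The direction of the ratios was read from the data and the column names. Each array's values correlated above 0 with the combined Dex-versus-Mock column of its time, whatever its dye (r from 0.168 to 0.706 across the tested probes). The control spot of the blank corner was above 0 on 10 of 10 arrays with Dex in Cy3 and below 0 on 9 of 10 arrays with Dex in Cy5, whereas a constant dye difference would give 1 sign on all arrays if the values were still Cy5 over Cy3. The values were therefore taken as already turned to 1 treatment direction, and that direction as Dex over Mock, which is likely and not stated per array.

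Control rows (57 of 32672) were left out. Between 4.42% and 32.6% of the probes of an array held exactly 0. These were treated as not measured, because a continuous log ratio is rarely exactly 0 and no header says what 0 stands for. The test used the 18763 probes with a ratio on all 20 arrays. The other 13852 probes, of which 131 were at 0 on all 20 arrays, enter only the alternatives. No intensity was used here, so no filter on dim spots could be set. All columns of per-array values were used. No pair of arrays held identical values (0).

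Values were divided by the log10 of 2 and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean for each of the 5 times and a dye term coded by the dye of the Dex sample, over all 20 arrays with 14 residual degrees of freedom. Each time was tested against 0, pairs of times against each other and each treated time against 0 h, with Benjamini-Hochberg adjustment over probes and a threshold of 0.05. The 4 arrays of a time come from sets that the labels call biologically independent. On simulated data with the spread, dye effects and layout of the 18763 tested probes, 2-fold changes were called for 90.0% of the changed probes at 2 h, 85.0% at 4 h, 87.0% at 8 h and 85.0% at 12 h, and 4-fold changes for 96.0% to 100% of them. The simulated errors were independent between arrays with a fixed spread per probe, and the dye effect was equally strong on all arrays. In the measured data the dye effect differed in strength between arrays and the spread differed between times. The shares called in the simulation may therefore be too high for the measured arrays. Plots were drawn with matplotlib 3.10.9.

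The design fixed before the data were examined assumed gene-level values. The files do not pair the custom probe identifiers with genes, and the gene table used here holds no such identifiers, so 0 of them matched. Averaging the probes of a gene, the tests of 16 gene lists with 330 members, the values of AP1 and the rule for named genes could not be applied, and each probe was tested by itself. In place of that rule, the named probes are the 2 with the largest mean rise and the 2 with the largest mean fall over the treated times among probes called at all 4 treated times with 1 sign on all 16 treated arrays. This replacement was set after the files were opened.

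The alternatives were centring, scaling, no dye term, each time fitted alone, robust moderation, array weights, other rules for missing ratios and small ratios, leaving out each set, the set number and the slide as blocks, a stricter threshold and a minimum fold. Keeping exact zeros, leaving out the 3 arrays with few zeros, removing each array's own dye slope and comparing late with early times were added after seeing the data. For the dye slope, each array's ratios were regressed on the dye effects estimated from the arrays of all other times and the fitted part was subtracted. The authors' combined ratios come with no p-value, so no count at the same threshold was made from them.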

Results

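Inflorescences of Arabidopsis thaliana plants that lack the functional floral regulators AP1 and CAL, and that carry a fusion of AP1 to the hormone-binding domain of the glucocorticoid receptor under a constitutive promoter, were profiled on two-colour Agilent arrays. AP1 is a MADS-domain transcription factor that specifies floral meristem identity, and in its absence, together with that of CAL, the plants make masses of inflorescence-like meristems in place of flowers. Dexamethasone, a synthetic steroid, binds the receptor domain and activates the fusion protein. The question of the design was how transcript levels changed in the hours after this activation. Each array held a dexamethasone-treated (Dex) and a mock-treated (Mock) sample of the same time and the same set. Tissue was taken at 0, 2, 4, 8 and 12 h, where the 0 h plants were untreated, and dexamethasone was given at 10 µM. There were 20 arrays, 4 at each time, from 4 sets of samples that the labels describe as biologically independent and number 2 to 5. Each sample came from about 25 plants. At each time the Dex sample carried Cy5 on 2 arrays and Cy3 on 2 arrays. The files give 1 log ratio per probe and array and no brightness, so the precision is limited by the number of arrays and cannot be related to signal. Of 32615 probes, 18763 had a ratio other than exactly 0 on all 20 arrays and were tested. The share of probes at exactly 0 ran from 4.42% to 32.6% of an array. The files do not pair the probes with genes, so results are given as counts of probes and for 4 probes by their identifiers. Log2 ratios below are of Dex over Mock and rest on a log base of 10 for the deposited values, which no header states.

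Before treatment, no probe passed the test for a difference between the plants assigned to Dex and to Mock. At 0 h limma called 0 of the 18763 probes at an adjusted p under 0.05, and 830 had an unadjusted p under 0.05, where chance alone gives about 938. The share of tested probes with the same sign on all 4 arrays was 12.5% at 0 h, and independent signs give 12.5%. Signs were not independent, as pairs of 0 h arrays with Dex in opposite dyes had a mean r of -0.12 across probes. This share therefore does not show that no difference was present. The 0 h counts are only a partial background for the treated times, because the 0 h arrays varied least. The root mean square residual was 0.26 at 0 h and 0.33 at 12 h. At 2, 4 and 8 h it was 0.29, 0.28 and 0.31. The test pooled the spread of each probe over all times. Relative to the spread of the time itself, it was therefore stricter at 0 h than at the treated times, most of all 12 h.

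After dexamethasone treatment, transcript levels differed from Mock at every treated time, and more probes fell than rose. All 20 arrays held plants with the fusion, so its activation cannot be told apart from other effects of dexamethasone. At 2 h 276 probes rose and 410 fell, 3.66% of those tested. At 4 h 253 rose and 383 fell, at 8 h 249 rose and 331 fell, and at 12 h 137 rose and 323 fell. The changes were mostly small. The median log2 ratio of the probes that rose was 0.49 at 2 h, 0.52 at 4 h, 0.48 at 8 h and 0.49 at 12 h, and that of the probes that fell was -0.62, -0.67, -0.68 and -0.63. A change of at least 2-fold was found for 90 of the called probes at 2 h (17 rose, 73 fell), 127 at 4 h (32 rose, 95 fell), 122 at 8 h (35 rose, 87 fell) and 94 at 12 h (21 rose, 73 fell). Of the called probes, 626 of 686 at 2 h, 601 of 636 at 4 h, 551 of 580 at 8 h and 435 of 460 at 12 h had the same sign on all 4 arrays, as the selection for a mean away from 0 favours. Over all tested probes that share was 20.7% at 2 h, 20.4% at 4 h, 20.7% at 8 h and 13.9% at 12 h, where independent signs give 12.5%. As the dye ties the signs of arrays, 12.5% is only a rough yardstick. The test was limma with a term for each time and 1 for the dye, fitted to all 20 arrays, with Benjamini-Hochberg adjustment. With each array centred on its median, 185 rose and 512 fell at 2 h, and after scaling the arrays to 1 spread 161 rose and 461 fell, so the share of rises at 2 h depended on the centring while falls outnumbered rises at all 4 treated times in each of these settings. The counts depended on single sets: without set 3 they were 97, 161, 160 and 81 at 2, 4, 8 and 12 h, without set 4 239, 264, 221 and 170, without set 5 207, 248, 168 and 172, and without set 2 372 at 8 h. Fitted alone on its 4 arrays, each time gave 0, 0, 0 and 1 call at 2, 4, 8 and 12 h, and after scaling to 1 spread the count was 359 at 8 h and 144 at 12 h. Array weights raised the counts, to 1501, 968, 683 and 1061 at 2, 4, 8 and 12 h.

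**Figure D1:**
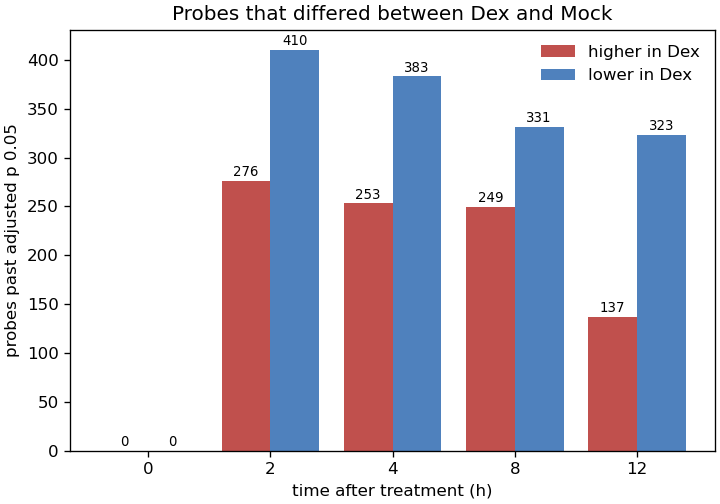
Bars give the number of probes past an adjusted p of 0.05 in limma at each time (h), higher in Dex (red) or lower in Dex (blue), among 18763 tested probes. At 0 h there were 0 in both directions, and at 2, 4, 8 and 12 h the blue bars (410, 383, 331 and 323) stood above the red ones (276, 253, 249 and 137).

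A group of 99 probes was called at all 4 treated times with the same sign on all 16 treated arrays, 25 of them higher and 74 lower in Dex. The 2 with the largest mean rise were CUST_26277_PI355422546 and CUST_6187_PI355422546. CUST_26277_PI355422546 had a log2 ratio of 2.03 ± 0.65 (SD, n = 4) at 2 h, 2.73 ± 1.3 at 4 h, 4.69 ± 0.72 at 8 h and 3.88 ± 1.16 at 12 h, with limma adjusted p of 0.0114, 0.0011, 1.05e-05 and 9.94e-05. At 0 h its ratio was 0.86 ± 0.56 (n = 4, limma adjusted p = 0.994), above 0 on all 4 arrays. CUST_6187_PI355422546 went from 0.31 ± 1.00 at 0 h to 1.73 ± 0.73 at 2 h, 1.97 ± 0.73 at 4 h, 4.66 ± 0.78 at 8 h and 4.09 ± 0.27 at 12 h, and its limma adjusted p at 8 h was 1.4e-06. The 2 with the largest mean fall were CUST_26434_PI355422546 and CUST_13686_PI355422546. CUST_26434_PI355422546 had ratios of -1.37 ± 0.59 at 2 h, -2.04 ± 0.78 at 4 h, -2.52 ± 0.73 at 8 h and -2.83 ± 0.87 at 12 h (limma adjusted p = 0.0421 at 2 h and 0.000444 at 12 h), against -0.39 ± 0.77 at 0 h. CUST_13686_PI355422546 had ratios of -1.46 ± 0.57, -1.53 ± 0.95, -2.17 ± 0.93 and -2.43 ± 0.50 at the same times (limma adjusted p = 0.0158 at 2 h and 0.000598 at 12 h), against -0.31 ± 0.22 at 0 h, below 0 on all 4 arrays. Scaling the arrays to 1 spread ended the 2 h call of all 4 probes, with the direction kept and limma adjusted p of 0.0769, 0.125, 0.139 and 0.082 in the order above. At 2 h CUST_26434_PI355422546 also lost its call with exact zeros kept as 0 (limma adjusted p = 0.0803) or with each array's own dye slope removed (0.0527). Fitted alone on its 4 arrays, each of 2, 4 and 8 h gave 0 calls, so all 4 probes lost their calls there. Leaving out single sets ended calls too, again with the direction kept. The selection for 1 sign on all 16 treated arrays largely fixed that direction in advance. At 2 h the limma adjusted p of CUST_26277_PI355422546 was 0.129 without set 3, 0.0996 without set 4 and 0.0714 without set 5, and that of CUST_6187_PI355422546 was 0.0526 without set 2, 0.0839 without set 3 and 0.054 without set 5. For CUST_26434_PI355422546 it was 0.0556, 0.162, 0.158 and 0.194 at 2 h without sets 2, 3, 4 and 5, and at 4 h 0.0814 without set 3 and 0.054 without set 5. For CUST_13686_PI355422546 without sets 3, 4 and 5 it was 0.215, 0.121 and 0.0696 at 2 h and 0.145, 0.17 and 0.154 at 4 h, and at 8 h it was 0.0504 without set 3.

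**Figure D2:**
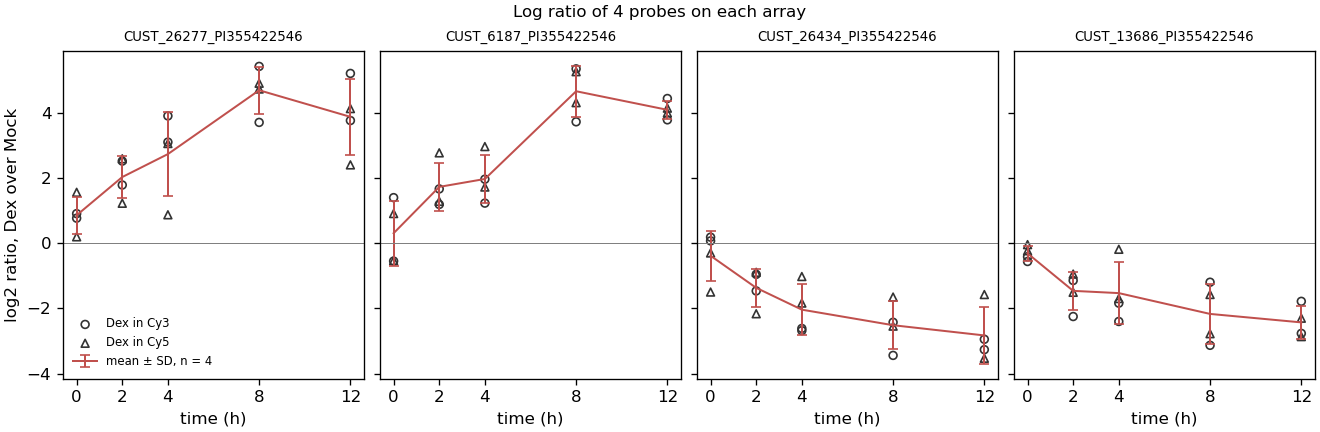
Each panel gives the log2 ratio of Dex over Mock (vertical axis) of 1 probe on each of the 20 arrays against time in h; circles are arrays with Dex in Cy3, triangles arrays with Dex in Cy5, and the red line joins means with the SD of 4 arrays. The means of the 2 left panels reached 4.69 and 4.66 at 8 h, and those of the 2 right panels reached -2.83 and -2.43 at 12 h.

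Calls made on 3 sets were then read in the array of the set left out, which played no part in making them. The probes kept their direction there in 72.3% to 98.8% of cases over the 16 combinations of set and treated time, with a median of 92.0%. In the 0 h array of the same set, the same probes had that direction in 36.2% to 63.5% of cases, with a median of 47.0%. The share at the treated time was 88.2% ± 10.7 (SD, n = 4) at 2 h, 91.4% ± 7.53 at 4 h, 91.0% ± 2.98 at 8 h and 87.8% ± 8.42 at 12 h. Over all tested probes the profiles were less repeatable. Between the mean of sets 2 and 5 and the mean of sets 3 and 4, Pearson's r across probes was 0.35 at 2 h, 0.47 at 4 h, 0.49 at 8 h and 0.17 at 12 h, and 0.21 at 0 h, and probes are not independent replicates. At 12 h the rank correlation of the same means was 0.01.

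The dye left a mark on many probes. Both dye orientations were equally common at each time, but across probes the fitted ratios still correlated with the dye term, with an r of 0.16 at 2 h, 0.17 at 4 h, -0.19 at 8 h and -0.30 at 12 h. The dye term was past the threshold in limma for 5694 probes (30.3%), 2836 higher and 2858 lower where Dex carried Cy5. At 0 h pairs of arrays with Dex in the same dye had a mean r of 0.28 across probes, and pairs with Dex in opposite dyes a mean r of -0.12. At 2 h these means were 0.30 and 0.17, at 4 h 0.32 and 0.13, at 8 h 0.36 and 0.05, and at 12 h 0.22 and 0.06. Without the dye term fewer probes were called, 415 at 2 h, 376 at 8 h and 285 at 12 h.

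**Figure D3:**
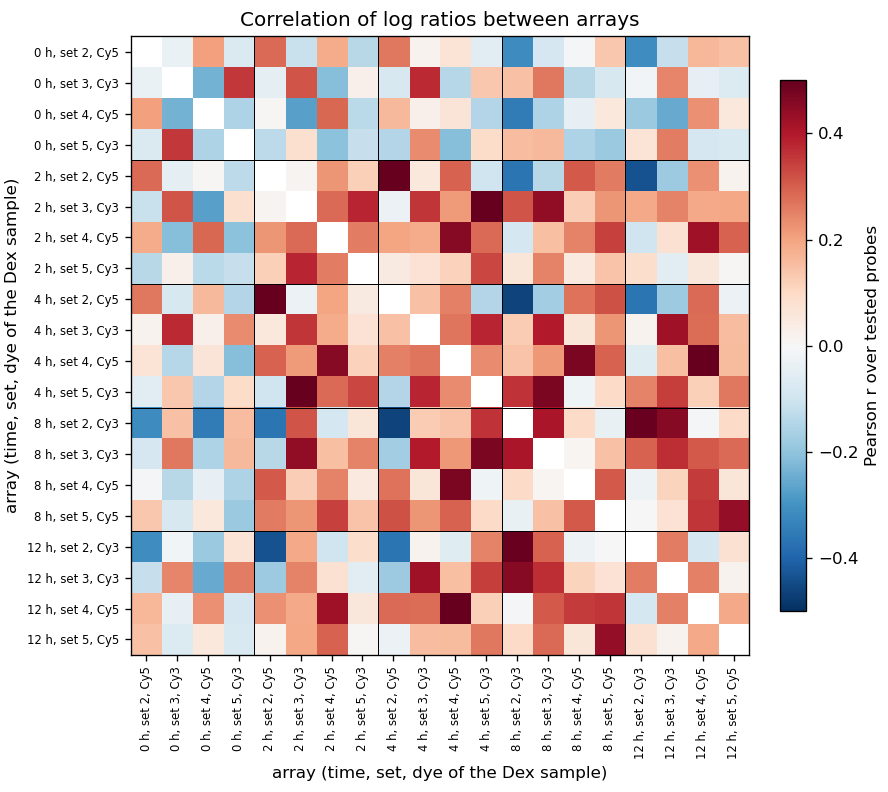
Colours give Pearson's r across the tested probes between each pair of the 20 arrays, ordered by time and set, with the dye of the Dex sample named on both axes; red is above 0, blue below 0 and the diagonal is left blank. At 0 h same-dye pairs had a mean r of 0.28 and opposite-dye pairs one of -0.12, and 98 of the 120 pairs of treated arrays were above 0.

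Probes that changed at one time often changed the same way at the next. Of the 276 probes that rose at 2 h, 102 also rose at 4 h, where independent lists would share 3.72, and of the 410 that fell at 2 h, 235 also fell at 4 h (8.37 for independent lists). Between 4 and 8 h 85 rises and 176 falls were shared (3.36 and 6.76), and between 8 and 12 h 75 rises and 169 falls (1.82 and 5.70). None of the probes called at consecutive times had opposite directions (0 for each of the 3 pairs). Of the rises at 2 h, 97.8% were above 0 at 4 h, and 59.1% were above 0 at 12 h. Of the falls at 2 h, 97.1% were below 0 at 4 h and 87.1% at 12 h. Each time had its own Dex and Mock samples, so no control sample was shared between the lists, although all lists shared the spread and the dye term of the fit. At 2 and 4 h the arrays of each set also shared a slide and a dye orientation. Pearson's r between mean profiles of the same sets was 0.49 for 2 and 4 h, 0.31 for 4 and 8 h and 0.50 for 8 and 12 h. Between disjoint sets it was 0.32, 0.31 and 0.35. The values for independent lists leave out such shared error. At an adjusted p under 0.01 the shared probes of both directions numbered 138, 120 and 118, against 337, 261 and 244 in the main setting. Over the 4 treated times 1436 probes were called at least once: 874 at 1 time, 310 at 2, 140 at 3 and 112 at 4. Of these, 620 only rose, 808 only fell and 8 rose at 1 time and fell at another. A call at 1 time and not at another is no test of a difference between the times.

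The difference between times was tested directly. No probe passed the threshold between 2 and 4 h, 4 and 8 h or 8 and 12 h in limma (0 each), and 671, 1536 and 723 had an unadjusted p under 0.05, where chance gives about 938. With slide as a fixed block 7 probes were called between 4 and 8 h, 3 with a higher and 4 with a lower ratio at 8 h. Between 2 and 12 h 78 probes differed, 29 with a higher and 49 with a lower ratio at 12 h. Of the 29, 21 had been called lower in Dex at 2 h and 11 were called higher in Dex at 12 h, and their median log2 ratio went from -0.45 to 0.22. Of the 49, 22 had been called higher in Dex at 2 h and 21 were called lower at 12 h, and their median went from 0.39 to -0.36. The fitted ratio had opposite signs at the 2 times for 21 of the 29 and 43 of the 49. Selection for a large difference between the 2 times itself favours opposite signs. These signs and medians are therefore no separate evidence of a reversed response. Centring each array on its median gave 49 higher and 39 lower. In sets 2 and 5 the Dex sample carried the other dye at 12 h than at 2 h. Across the tested probes the difference correlated with the dye term, with an r of -0.35. With each array's own dye slope removed 50 of the 78 stayed called, so a share of dye in the difference is not excluded. With slide as a fixed block 0 of the 78 stayed called and 1 other probe was called. The count fell to 30 without the dye term, to 0 without set 2, without set 3 or without set 5, to 37 without set 4, and to 0 without the 3 arrays with few exact zeros, of which 2 are in this comparison (set 5 at 2 and at 12 h), a setting chosen after seeing the data. In the limma fit with the slide block, all 78 kept their direction, 75 had an unadjusted p under 0.05 and their median difference was 0.65 against 0.72. The selection of the 78 on the same arrays favours these values. Only 1 slide held arrays of both times, and no slide held more than 1 array of a time, so a slide on its own gives no spread between arrays.

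Taking the 0 h difference off, 57 probes rose and 95 fell at 2 h, 56 rose and 91 fell at 4 h, 84 rose and 76 fell at 8 h, and 32 rose and 67 fell at 12 h. This comparison asks for a change beyond that of the untreated plants and carries the spread of both times, with a median standard error of 0.14 against 0.10 on the log2 scale for a single time. At 2 h centring each array gave 50 rises and 151 falls. Without set 3 the counts of both directions were 2, 8, 23 and 4 at 2, 4, 8 and 12 h, without set 4 they were 17, 17, 27 and 8, without set 5 they were 14, 21, 11 and 7, and without set 2 the count at 8 h was 68, against 152, 147, 160 and 99 with all sets. With slide as a random block they were 254, 218, 350 and 115, and at 8 h 216 rose and 134 fell. Array weights gave 898, 473, 667 and 604. Without the dye term 74, 85, 80 and 22 were called, with exact zeros kept as 0 they numbered 73, 84, 82 and 35, and without the 3 arrays with few exact zeros 82, 57 and 38 at 2, 4 and 12 h. With dye slopes removed 105 were called at 8 h and 30 at 12 h, and at 12 h a ratio on at least 2 arrays of each time gave 46 and scaling the arrays to 1 spread left 0.

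The authors' deposited table of combined ratios gives 1 value per probe and time, with no error. Across the tested probes, its values and the fitted log2 ratios had an r of 0.49 at 0 h, 0.81 at 2 h, 0.80 at 4 h, 0.78 at 8 h and 0.73 at 12 h. Both rest on the same arrays, so this compares 2 ways of averaging. Every called probe (100% at each treated time) had the same sign in the authors' deposited table. In the authors' deposited table, ratios of at least 2-fold among the tested probes numbered 71 up and 150 down at 2 h, 62 and 196 at 4 h, 79 and 195 at 8 h, and 56 and 186 at 12 h, against 24 up and 25 down at 0 h. Over all its probes the same counts were 235 up and 328 down at 2 h, 257 and 443 at 4 h, 306 and 532 at 8 h, and 190 and 350 at 12 h, against 203 and 98 at 0 h, so at 12 h fewer probes were up there than before treatment.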

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

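The tests of centring, of left-out probes, of dye strength and of slides below were chosen after the results were seen. The criteria for dye strength, slides and left-out probes were also set or changed after values of these tests had been seen, and a first dye slope test, which could not have moved the mean of a time, was replaced. The splits, the turned array and the test of a single set were set out before their results.

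One array stood apart from the other 3 of its time in 1 of the 39 groups of 4 values examined, where chance gives about 1 in 20. At 2 h, 6.0% of the probes of set 5 were at exactly 0, against 25.3% to 27.9% in the other sets. The 4 h array of set 4 (5.19%, against 23.5% to 28.0%) and the 12 h array of set 5 (4.42%, against 26.6% to 31.7%) were nearly as far apart and fell just short of the criterion. Of the 13852 probes outside the main test, some were called with zeros kept as 0. They numbered 39 at 2 h, 28 at 4 h, 41 at 8 h and 8 at 12 h, against 0 at 0 h. The main comparisons do not use these probes. Among the tested probes 3.66% were called at 2 h in the main fit. Whether the calls outside the main test are a signal was not tested.

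Between 2 and 12 h 78 probes differed. Of the 35 splits of these 8 arrays into 4 and 4, only 1, the real one, called as many, and the highest other split called 1. That share is under 0.05 if arrays exchange freely, but the layout ties them to sets, slides and dyes. Exchanges within sets give 8 splits, too few for a share under 0.05, and the highest other called 0. Chance is therefore not excluded. Without the 3 arrays with few exact zeros, of which set 5 at 2 and 12 h belong here, 0 probes were called. Dye bias of unequal strength between arrays is argued against as the whole cause: after each array's own dye slope was removed, 50 of the 78 stayed called and their median difference in the original direction was 0.72, as before, although the correlation of the difference with the dye term across probes went from -0.35 to 0.02. Slides that differ between the times stay open. With slide as a fixed block in limma the median difference was 0.65, all 78 kept their sign and 75 had an unadjusted p under 0.05. The selection of the 78 on the same arrays favours these values, and only 1 slide held both times. Of the 78, 0 stayed called, and the median standard error went from 0.13 to 0.18 with 8 residual degrees of freedom. A single set stays open, since the 78 leading probes of the other 3 sets kept their sign in the set left out in 69.2% of cases for set 5, 74.4% for sets 2 and 4 and 89.7% for set 3. A partial share of dye also stays open, as does a dye bias that departs from the dye profile of the other times. A change of the response between the times, which the design names, stays open too.

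More probes fell than rose at 2, 4, 8 and 12 h. Falls still outnumbered rises at 4 of 4 times after centring the arrays and at 4 of 4 with the dye slopes removed. This argues against array medians away from 0 and against dye bias of unequal strength along the dye profile of the other times. A dye bias of another form was not tested. With all 32615 probes tested and zeros kept as 0 (168 rises and 310 falls, 195 and 311, 170 and 273, 96 and 196), and with the 22253 probes that had a ratio on at least 2 arrays of each time (205 and 357, 220 and 343, 217 and 318, 112 and 264), falls also led at 4 of 4 times. Most calls with zeros kept as 0 were also calls of the main fit: 439 of 478, 478 of 506, 402 of 443 and 284 of 292 at 2, 4, 8 and 12 h. The same held under the other rule (536 of 562 at 2 h). The added probes could hardly turn the balance, so this test does not decide whether the choice of probes is a cause. That test took the place of an earlier one on the left-out probes alone, which was undecided, as falls led there at 2 of 4 times, with 17 rises and 22 falls at 2 h, 18 and 10 at 4 h, 9 and 32 at 8 h and 4 and 4 at 12 h. Above the 0 h difference the balance turned at 8 h, with 84 rises and 76 falls, and 216 and 134 with slide as a random block and 396 and 271 with array weights, but 71 and 92 after centring. With 8 splits of the signs of 4 arrays no share under 0.05 can be had at a single time: the real counts were 0, 686, 636, 580 and 460 at 0, 2, 4, 8 and 12 h, the highest others 0, 0, 1, 29 and 67, and 8, 1, 1, 1 and 1 splits gave as many as the real one. At 8 h the split with 29 calls was the one that follows the dye. An excess of transcripts lowered by the activated fusion is a hypothesis that these tests leave open, and other technical causes were not tested.

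At 0 h the mean ratios of untreated plants correlated between independent sets across the tested probes, although no probe was called. The r was 0.21 between sets 2 and 5 and sets 3 and 4. Pairs of 0 h arrays with Dex in the same dye had a mean r of 0.28, and pairs in opposite dyes one of -0.12. With each array's own dye slope removed r was still 0.21. This argues only against bias of unequal strength along the dye profile of the other times. A dye bias of another form at 0 h would pass this test and stays open. Whether 1 array runs the wrong way cannot be told from correlations: with the dye removed, the lowest correlation of a 0 h array with the mean of the other 3 was -0.0236, in set 4, and the others were 0.13 to 0.15. The dye slopes argue against a ratio turned against its labelled dye, which would reverse its slope. At 0 h they were 0.44, -0.25, 0.29 and -0.30 in sets 2, 3, 4 and 5, each with the sign of its dye. The design gives no biological group within 0 h other than the later assignment to Dex or Mock, so no biological explanation was tested.

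Between neighbouring times the real splits called 0 probes, so all 35 of the 35 splits gave as many in each of the 3 comparisons. The highest other splits called 19 between 2 and 4 h, 330 between 4 and 8 h and 16 between 8 and 12 h. The 330, against 0 in the real split, point to a structure of the samples: that split placed the 8 h arrays of sets 2, 4 and 5 and the 4 h array of set 4 against the rest. For the changes above the 0 h difference, 1 of 35 splits, the real one, gave as many calls at each of 2, 4, 8 and 12 h (152, 147, 160 and 99), and the highest others called 0, 0, 1 and 0. That share is under 0.05 if arrays exchange freely, but the layout ties them to sets, slides and dyes, so chance is not excluded. At 12 h scaling the arrays left 0 calls. Arrays of 1 set shared a slide at most of these times, and exchanges within sets give 8 splits, too few for a share under 0.05; the highest others among these also called 0, 0, 1 and 0.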

How the results depend on the processing

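At 0 h 0 probes were called in limma under each of the 19 alternatives run. The 4 named probes kept their direction in all 192 alternatives of their treated times. Their selection for 1 sign on all 16 treated arrays largely fixed this direction in advance. The call was lost in 26 of these alternatives, with a limma adjusted p of up to 0.215. Fitting each time alone was not among the 192 and called 0 probes at 2, 4 and 8 h, so each named probe lost its calls there. Of the 154 alternatives to a main count above 0, 67 stayed within 1.5 times of it and 87 moved further; of the 52 to a main count of 0, 50 were also 0. Keeping exact zeros, leaving out the 3 arrays with few of them and removing dye slopes were chosen after seeing the data. The causes of the following changes were not tested, except that stricter thresholds call fewer probes by construction. Times are given in order of 2, 4, 8 and 12 h.

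Leaving out 1 set in turn, the counts ran from 97 to 798 at 2 h, 161 to 720 at 4 h, 160 to 372 at 8 h and 81 to 386 at 12 h, from 0 to 37 for 12 h against 2 h, and above the 0 h difference from 2 to 207, 8 to 151, 11 to 68 and 4 to 70. Fitting each time alone on its 4 arrays called 0, 0, 0 and 1. Scaling the arrays called 359 at 8 h, 144 at 12 h and 0 at 12 h above 0 h. Without the dye term 415 were called at 2 h, 376 at 8 h, 285 at 12 h, 30 between 12 and 2 h, and 74, 85, 80 and 22 above 0 h. Array weights gave 1501, 968 and 1061 at 2, 4 and 12 h, with 683 at 8 h, so the order of the times was not stable, and 898, 473, 667 and 604 above 0 h. With a ratio on at least 2 arrays of each time 46 were called at 12 h above 0 h. Slide as a random block gave 254 and 350 at 2 and 8 h above 0 h, and as a fixed block 7 between 8 and 4 h and 1 between 12 and 2 h. An adjusted p under 0.01 left 247, 299, 227 and 167, with 138, 120 and 118 shared between consecutive times, and a change of at least 2-fold left 90, 127, 122 and 94. With exact zeros kept as 0, 292 were called at 12 h, 33 between 12 and 2 h, and 73, 84, 82 and 35 above 0 h. Without the 3 arrays with few zeros 321 were called at 2 h, 299 at 4 h, 0 between 12 and 2 h, and 82, 57 and 38 at 2, 4 and 12 h above 0 h. With dye slopes removed 105 and 30 were called at 8 and 12 h above 0 h.

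Arrays of 1 set shared a slide at most times and 1 dye orientation at 0, 2 and 4 h, but the labels name no shared plants or day for a set. The values paired them at most in part. With the dye removed, 11 of 40 pairs of arrays of 1 set correlated over 0.1 across probes (range -0.21 to 0.37), and 7 of the 20 arrays correlated best with their own set. With the dye left in, mean profiles of the same sets had an r of 0.49 for 2 and 4 h, 0.31 for 4 and 8 h and 0.50 for 8 and 12 h. Between disjoint sets it was 0.32, 0.31 and 0.35, so error shared within a set is not excluded. With the set number as a replicate block 950 probes were called at 8 h, 119 between 12 and 2 h, 1 between 8 and 4 h, and 236, 227, 355 and 188 above 0 h (227 rose and 128 fell at 8 h); at 2, 4 and 12 h it called 900, 843 and 602, and the 2 h adjusted p of CUST_26434_PI355422546 was 0.0563. Gene averages, gene lists, AP1 and counts from the authors' combined ratios were not run, for want of gene names or p-values, and signal over background was not used here.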

Other observations

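The comparison of late with early times was chosen after the results were seen. With the mean of 8 and 12 h set against the mean of 2 and 4 h, limma called 222 probes, 85 higher and 137 lower at the late times. The median log2 ratio of the 85 went from -0.30 to 0.20, and that of the 137 from 0.29 to -0.26. Selection for a large difference between late and early times itself favours medians on opposite sides of 0. With each array's own dye slope removed 122 probes were called, 48 higher and 74 lower at the late times. The dye of the Dex sample in sets 2 and 5 was the other one at 8 and 12 h than at 0, 2 and 4 h.

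The dye slopes differed in size between arrays, from 0.03 on the 12 h array of set 5 to 0.85 on the 8 h array of set 2, and had the sign of the dye on 20 of 20 arrays. Array weights in limma ran from 0.267 (12 h, set 2) to 2.53 (0 h, set 5).

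The probe identifiers fall into 2 series. Of 6049 probes in the smaller series 14.9% had a ratio on all 20 arrays, against 67.2% of 26566 in the larger one. Of those tested, 23 of 902 (2.55%) and 1413 of 17861 (7.91%) were called at 1 or more treated times.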
